A study of Mus musculus with 9 samples.

How the data were processed

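The 9 deposited libraries were all of CD45 and CD11b positive leukocytes sorted from wild-type C57BL6/N mice. Per the labels' protocols, marrow was flushed from the femur, blood was drawn by cardiac puncture and its red cells lysed for 4 minutes, lung was digested with liberase and DNase for 45 minutes at 37 °C, and spleen was mashed through a mesh. Only the lung was digested with enzymes. Per the labels' protocols the libraries were made with the Chromium Single Cell 3' v2 kit. The files the authors deposited hold raw UMI counts per gene and cell barcode, with no normalization. The submitters' processing notes name Cell Ranger 2.1.1, Seurat 3.0 and the build mm10, without role or order; the filter that left the deposited barcodes is not given in the sources used here. Barcode and gene lists were text only. In blood ZT13 replicate 2 the matrix had 3388 columns and the barcode list 3204 entries, so cells were taken by column number.

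Of 27998 gene IDs, 27645 (98.7%) were found in the GENCODE vM21 annotation of GRCm38 (mm10), from which coordinates were taken; the genes whose coordinates are given are protein coding there, and positions are those of the whole gene. Symbols are those paired with the IDs in the deposited gene lists. Genes that share reads with close copies, such as Bcl2a1b, Stfa2l1 or ribosomal protein genes, have uncertain counts, since the handling of such reads is not given in the sources used here.

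Cells with at least 200 genes and at most 10% mitochondrial UMIs were kept; 425 barcodes of blood ZT5 and 97 of blood ZT13 replicate 1 had too few genes. Doublets called by Scrublet in scanpy 1.11.5 were removed per library. Its automatic threshold called 2 of 7367 cells in marrow replicate 2 and 10 of 7542 in blood ZT5, and so did not work there. Removing the highest scores at 0.8% per 1000 barcodes was therefore added as an alternative. Cells of all libraries were clustered together on 2000 variable genes, 30 principal components and 15 neighbours, with Leiden clustering (leidenalg 0.10.2) at resolution 1.0 and seed 7. Clusters were named from 18 marker classes, by at least 3 markers of a class among their top 50 genes by fold and no more markers of another class than of their own among the top 10; others stayed unnamed. Cluster 6 held T cell, plasma cell and airway club cell transcripts, so no T cell shares are given. Neutrophil-like cells are mature and immature clusters together, so the makeup of this class can differ between libraries. Markers used to name clusters are not independent evidence about these classes.

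Counts were summed over the cells of a class in each library, with at least 20 cells per sum, and the sums were tested with edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr) in R 4.3.3. One model of 5 groups covered all 9 libraries, with 4 residual degrees of freedom, a prior of 13.4 degrees of freedom and a biological coefficient of variation of 0.326. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Groups with 1 library take their spread from the others. Values are CPM. Gene levels in neutrophil-like sums are counts scaled to the library total times its TMM factor. That factor ran from 0.707 in blood ZT13 replicate 1 to 1.403 in lung replicate 2. Summed marker CPM and the level of Scgb1a1 are scaled to the library total alone. Log2 differences are the shrunken estimates of the fit, and SD is over libraries. Each standard error was derived as the unshrunken log2 difference divided by the square root of the quasi-likelihood F statistic. Where a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with a 95% counting interval; both cover counting error only. Replicates of a group differed by far more than sampling noise (chi-square per degree of freedom from 9.74 in the spleen to 55.5 in the marrow), so none were counted as duplicates.

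The 16 gene lists were granules (primary, secondary, gelatinase), cell cycle, trafficking receptors, interferon response, inflammatory NF-kB, immediate early and heat shock, angiogenesis and growth factors, glycolysis and hypoxia, oxidative phosphorylation, NADPH oxidase, antigen presentation, survival and apoptosis, circadian clock, and ribosomal proteins. The last, by its rule on symbols, also took in the kinases Rps6ka1, Rps6ka4 and Rps6kc1 and the gene Rps27rt. Each list was tested in the 7 comparisons with camera in limma 3.58.1, with a preset correlation of 0.01 and a prior count of 3, and the 112 tests were adjusted together. This test sets a list against all other genes, so its direction is relative to them and need not follow the sign of the list's median. Of the 51 that passed, 0 did with an estimated correlation. Some lists shared genes with the markers: 2 of 7 gelatinase genes with mature and 1 with immature neutrophils, 1 of 19 trafficking receptors each with mature neutrophils and endothelium, 1 of 26 interferon genes with plasmacytoid dendritic cells, 1 of 26 immediate early genes with monocytes and 1 of 18 angiogenesis genes with mature neutrophils; the larger overlaps stand beside the results.

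Groups, comparisons, gene lists, markers, thresholds, and the alternatives not said to be added later were chosen before the data were examined. By a rule also set then, the genes named were the 10 largest rises and falls per comparison against blood ZT13 and for lung against spleen. They had to be called, have a mean logCPM of at least 5 and show no overlap between the libraries of the groups. Markers of other classes were left out, and so were genes whose CPM was under 10% of that in the other cells of the library, as possible free RNA. The free RNA rule left out 0 genes in the neutrophil comparisons and was not applied to monocyte-like cells. Smaller sets had 5 each way, and 4 members of each list with the smallest adjusted p were added. These list members were not put through the rules on overlap, markers of other classes and free RNA. Alternatives were DESeq2 1.42.0, its size factors in edgeR, no low-count filter, no cell filter, at least 500 UMIs per cell, doublets kept, sums thinned to the smallest library, only the groups compared, the replicate number as a block, leaving out each library, mature clusters alone, blood as one group, and an estimated correlation. Added after seeing the data were doublets at the expected rate, Leiden resolution 0.5 for gene counts, leaving out the ZT5 library, and list tests in mature clusters alone.

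The procedure was tested on simulated counts with 100 genes seeded at each fold. Of genes changed 4-fold it recovered 65% for marrow against blood (6735 genes), 13% for lung (7088), 33% for spleen (7121) and 22% for ZT5 (7218); of genes changed 2-fold it recovered 6%, 1%, 3% and 1%. False calls made up 13.4%, 12.5%, 16.3% and 14.8% of the calls, above the nominal level, so single calls near the threshold carry more error than their adjusted p states. The lung sums were the smallest, and a gene not called there may differ by several fold. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.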

Results

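The series asked how neutrophils, short-lived granulocytes made in the bone marrow, differ between the tissues they enter. Leukocytes positive for CD45, a pan-leukocyte surface protein, and CD11b, an integrin chain of myeloid and natural killer (NK) cells, were sorted from wild-type C57BL6/N mice aged 10 to 15 weeks and profiled by droplet-based 3' single-cell RNA sequencing. The 9 libraries fell into 5 groups by tissue label: 2 libraries each of bone marrow, lung, spleen and blood taken at ZT13, and 1 library of blood taken at ZT5, the time codes being given as in the labels. Total depth ranged from 3287027 unique molecular identifiers (UMIs) over 961 barcodes in lung replicate 1 to 30763155 over 7382 barcodes in bone marrow replicate 2. The lung held the least material for the comparisons made here. Its summed neutrophil-like cells gave 98993 and 55845 UMIs, against 9679149 and 17659141 in the marrow. Those of blood ZT13 gave 1189926 and 1279707, those of blood ZT5 473664, and those of the spleen 131747 and 1120487. The labels do not say whether the libraries of a tissue came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

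Neutrophil-like cells, the union of clusters led by mature markers such as Retnlg, Mmp9 and Csf3r or immature markers such as Ltf, Camp and Fcnb, dominated the marrow libraries, at 73.4% (95% exact interval 71.1 to 75.6) and 70.2% (69.1 to 71.2) of kept cells. In blood ZT13 they made up 36.4% (33.8 to 39.1) and 29.2% (27.7 to 30.8), and in the single ZT5 library 3.54% (3.14 to 3.99). The spleen libraries held 4.43% (3.42 to 5.64) and 4.82% (4.29 to 5.40), and the lung libraries 9.94% (8.10 to 12.0) and 0.930% (0.624 to 1.33). Intervals cover counting error only. The sort, the dissociation and the cell number also set these shares. So may the depth at which the deposited barcodes were cut. The lowest barcode held 767 and 1215 UMIs in the lung libraries, 1272 and 869 in blood ZT13, 1172 in blood ZT5 and 4149 and 1398 in the marrow libraries. Neutrophil-like cells had a median of 979 UMIs in lung replicate 1 and 1147 in blood ZT13 replicate 2. Cells of that depth would be missing from lung replicate 2, blood ZT5, blood ZT13 replicate 1 and the marrow libraries. Shares can therefore not be compared freely between libraries. The cut also sets which cells enter the sums, so the gene comparisons and the shares of immature cells carry the same limit. As 2 libraries against 2 cannot give a two-sided exact permutation p below 0.333, shares were not tested between tissues. NK-like cells ranged from 0.205% (0.0422 to 0.597) in marrow replicate 1 to 45.8% (44.7 to 46.9) in blood ZT5. Monocyte-like cells ranged from 0 of 1466 cells in marrow replicate 1, which allows a share of up to 0.205%, to 48.9% (45.7 to 52.2) in lung replicate 1. That limit holds for this naming of clusters only: at Leiden resolution 0.5, 6 cells of marrow replicate 1 (0.409%) were monocyte-like, and an unnamed cluster with the monocyte marker F13a1 among its leading genes held 305.

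**Figure D1:**
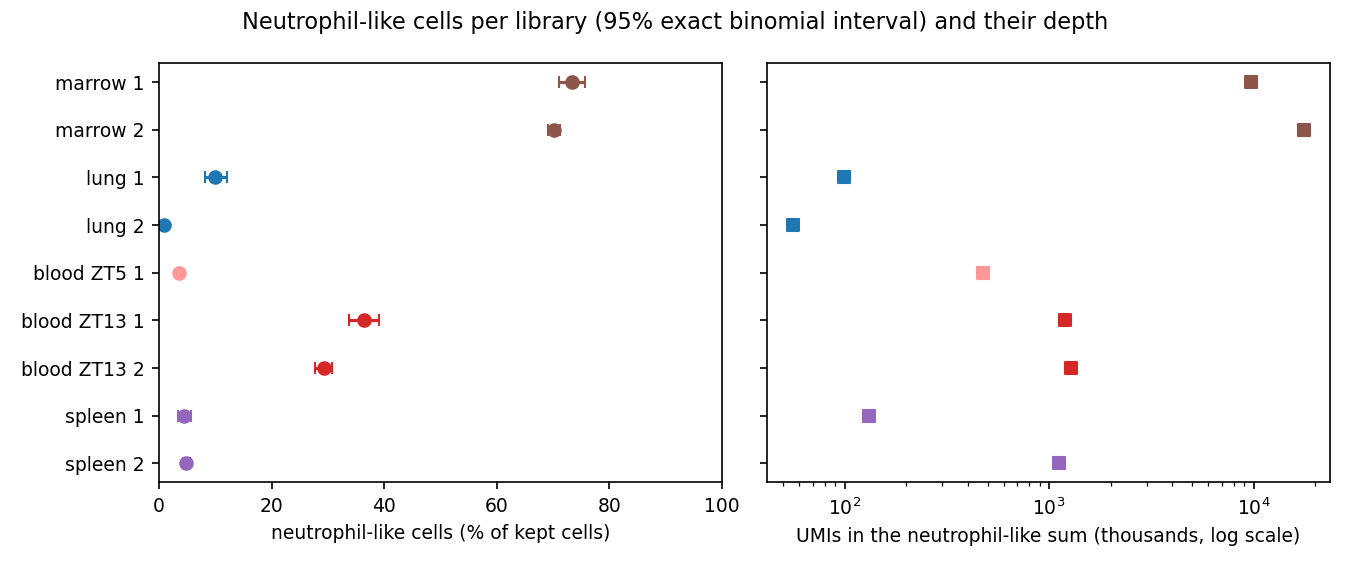
Left, neutrophil-like cells as a percentage of kept cells in each of the 9 libraries, with 95% exact binomial intervals; right, UMIs in the summed neutrophil-like cells of each library in units of 1000, on a log scale. The marrow libraries sit at 73.4% and 70.2%, while lung replicate 2 has 0.930% and the smallest sum, 55845 UMIs.

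The first comparison set marrow neutrophils, where the cells are made, against those circulating at ZT13. Marrow cells carried far more transcripts of primary and secondary granule proteins and of the cell cycle, and blood cells more of adhesion, chemoattractant receptor and interferon-response genes. Fcnb (ENSMUSG00000026835, chromosome 2, 28076378 to 28084885, GRCm38), which encodes a ficolin of the specific granules, averaged 539 ± 204 CPM (UMI counts scaled to the TMM-adjusted library total, SD, n = 2) in the marrow and 0 in both blood libraries, at least 410-fold higher against a floor of 3 counts over the group. Elane (chromosome 10, 79886247 to 79888215), neutrophil elastase, was at least 322-fold higher at 423 ± 75.2 CPM (SD, n = 2). Ltf, the iron-binding lactoferrin, rose by 6.32 ± 1.43 log2 units (SE; adjusted p = 0.00445). Its level was 9553 ± 840 CPM in the marrow and 119 ± 94.0 in blood (SD, n = 2). Of 7942 genes tested with edgeR, 1686 were called, 780 higher and 906 lower in the marrow, at a Benjamini-Hochberg adjusted p under 0.05. Without marrow replicate 1 the count was 778 and without marrow replicate 2 it was 513, and 56 and 44 of 69 called genes chosen by the rule for named genes stayed called.

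Of 7 genes on the primary granule list, named for the earliest granules, 6 rose and 1 fell, with the same numbers when adjusted over the list alone. Ms4a3 was at least 111-fold and Mpo, myeloperoxidase, at least 140-fold higher. The list moved up as a whole, with a median log2 difference of 7.60, or 6.79 with genes at 0 set to their bound (camera adjusted p = 1.52e-05; adjusted p = 0.199 with an estimated correlation). Secondary granule genes rose in 7 of 10 cases, 8 when adjusted over the list alone, among them Chil3, a chitinase-like lectin (4.71 ± 1.07), and Orm1, an acute-phase glycoprotein (5.20 ± 0.74). The list's median was 4.95 (camera adjusted p = 0.00043; adjusted p = 0.505 with an estimated correlation). These lists overlap with the markers used to name cells: 9 of the 10 secondary granule genes were markers of immature neutrophils and 6 of the 7 primary granule genes were markers of granulocyte-monocyte progenitors. Cell cycle genes rose in 23 of 24 cases, also when adjusted over the list alone, with a median of 6.40, or 5.45 with bounds (camera adjusted p = 9.37e-29; adjusted p = 0.199 with an estimated correlation). Ube2c, an ubiquitin-conjugating enzyme of mitotic exit, was at 306 ± 2.01 CPM in the marrow (SD, n = 2) and 3 counts in blood, a ratio of 233 (95% counting interval 79.7 to 1130). Rrm2, a subunit of ribonucleotide reductase, was at least 120-fold and Mki67, a marker of cycling cells, at least 47.7-fold higher. The makeup of the sums differed: immature neutrophil-like cells were 15.1% and 66.5% of the neutrophil-like cells in the marrow libraries, and 0 and 6 cells in the blood ZT13 libraries. Cluster 0 held 84.2% of these cells in marrow replicate 1, and clusters 5, 1 and 3 held 49.1%, 32.9% and 17.4% in replicate 2. Clusters 32 and 24 held 99.4% and 98.4% in the blood libraries. In mature clusters alone, 296 of 4832 genes were called, 79 higher and 217 lower. There 5 of 6 primary granule, 2 of 10 secondary granule and 3 of 10 cell cycle genes still rose. The split into mature and immature cells depended on the clustering. At Leiden resolution 0.5, immature clusters held 4243 and 899 cells of marrow replicate 2 and 229 and 51 of spleen replicate 2. At resolution 1.0, 3437 and 231 cells of these libraries were immature. Mature clusters alone were not tested at resolution 0.5.

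Interferon-response genes were lower in marrow than in blood neutrophils in 22 of 26 cases, 23 when adjusted over the list alone, with a median of −2.58 (camera adjusted p = 9.25e-14; adjusted p = 0.199 with an estimated correlation). Gbp2, an interferon-induced GTPase, fell by 5.15 ± 0.52 log2 units (SE, n = 2 per group). The ubiquitin-like Isg15 and the nucleic acid sensor Zbp1 fell by 2.87 ± 0.44 and 3.09 ± 0.41. Of 18 trafficking receptors, 9 fell, 12 when adjusted over the list alone, with a median of −1.46 (camera adjusted p = 8.96e-05; adjusted p = 0.199 with an estimated correlation). Among them was Cxcr2 (chromosome 1, 74153989 to 74161246), the receptor for chemokines that release neutrophils from the marrow, at 159 ± 63.0 against 983 ± 389 CPM (SD, n = 2; log2 −2.62 ± 0.59, adjusted p = 0.00438). Selplg, the main selectin ligand, fell by 2.75 ± 0.52. The Cxcr2 call was lost without marrow replicate 2. Antigen presentation genes fell in 9 of 16 cases, also over the list alone (median −1.70, camera adjusted p = 0.000126; adjusted p = 0.442 with an estimated correlation). They included H2-Aa and H2-D1, and 4 of the 18 listed genes were dendritic cell markers. Immediate early and heat shock genes fell in 8 of 24 cases, 11 over the list alone (−1.25, camera adjusted p = 0.000683; adjusted p = 0.413 with an estimated correlation). Ier5 led them (−3.81 ± 0.67). Inflammatory NF-kB genes fell in 7 of 23 cases, also over the list alone (−0.88, camera adjusted p = 0.00586; adjusted p = 0.516 with an estimated correlation). Survival genes such as Mcl1 fell in 4 of 16, 5 over the list alone (−1.13, camera adjusted p = 0.0102; adjusted p = 0.199 with an estimated correlation). In mature clusters alone these last lists no longer passed (camera adjusted p = 0.185 and 0.108). Markers of other cells moved with these groups: 13 of 14 NK, 7 of 7 platelet, 5 of 5 erythroid, 9 of 20 monocyte and 4 of 9 dendritic cell markers were lower in the marrow sums, and 7 of 9 progenitor markers were higher.

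Metabolic lists were set against blood in the same way. Oxidative phosphorylation genes rose in 5 of 29 cases, 3 when adjusted over the list alone, with a median of 0.88 (camera adjusted p = 0.000113; adjusted p = 0.516 with an estimated correlation). Ribosomal protein genes rose in 6 and fell in 2 of 92, 2 and 1 over the list alone (0.60, camera adjusted p = 1.52e-05; adjusted p = 0.661 with an estimated correlation). Of 6 NADPH oxidase genes, whose products make the respiratory burst, 2 rose, Cybb by 3.09 ± 0.66 and Ncf1 by 1.58 ± 0.41 (list camera adjusted p = 0.101). Gelatinase granule genes fell in 2 of 7 cases (camera adjusted p = 0.244) and glycolysis genes rose in 3 and fell in 2 of 19 (0.453). In the angiogenesis list 1 gene of 11 rose, the semaphorin and VEGF coreceptor Nrp1 (0.453). Of 5 clock genes Per2 fell (0.403). Adjusted over the list alone, these counts were the same except for the clock list, where 2 genes fell. Among the largest falls outside the lists were Wfdc17 (−8.00 ± 1.16), the metalloreductase Steap4 (−7.99 ± 0.76) and Cd244 (−7.93 ± 0.81), while the platelet-expressed genes Nrgn, Myl9 and Alox12 were at 0 in both marrow libraries.

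**Figure D2:**
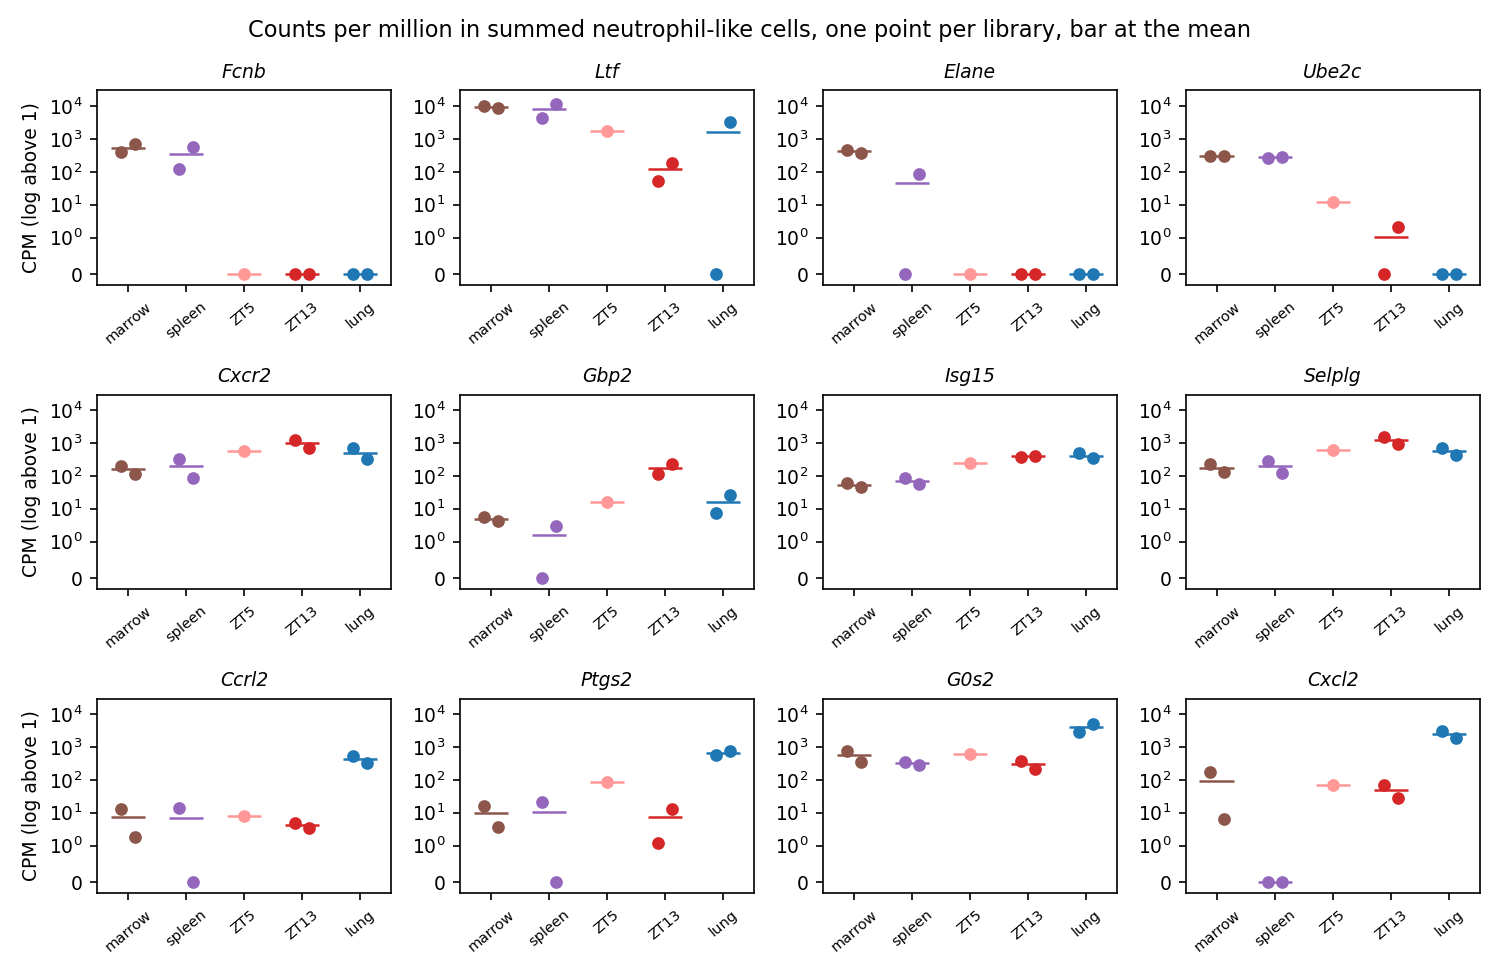
Expression in CPM (counts scaled to the TMM-adjusted library total) of 12 genes in summed neutrophil-like cells of each group, 1 point per library and a bar at the group mean, on an axis that is linear up to 1 and logarithmic above. Fcnb and Elane were detected in marrow and spleen libraries alone, and Ccrl2, Ptgs2 and Cxcl2 stood highest in both lung libraries; Elane was at 0 in spleen replicate 1.

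Spleen neutrophils were compared with the same blood libraries. They too carried more primary and secondary granule and cell cycle transcripts than blood neutrophils. Fcnb averaged 350 ± 318 CPM (SD, n = 2), at least 266-fold higher, Ltf rose by 6.06 ± 1.41 log2 units (adjusted p = 0.0128). Ube2c stood at 274 ± 15.5 CPM (SD, n = 2), a ratio of 215 (95% counting interval 72.9 to 1050). Cxcr2 fell by 2.37 ± 0.61, Selplg by 2.60 ± 0.53 and Isg15 by 2.54 ± 0.46 log2 units. In edgeR 792 genes were called, 427 higher and 365 lower, which is 53.9% higher; with DESeq2 size factors the share was 68.8%. That scaling moved the median of all genes by 0.21 log2 in this comparison. The shift was 0.24 for lung against blood, 0.17 for lung against marrow and −0.13 for marrow against spleen. The calls rested largely on spleen replicate 2, in which 81.3% of neutrophil-like cells were immature, against 36.5% in replicate 1. Without it 24 genes were called, 10 of 58 named genes among them, with Ltf, Cxcr2, Selplg and Isg15 lost. Without blood ZT13 replicate 1, 44 of 58 named genes stayed called. In mature clusters alone no gene was called, with 249 genes at an unadjusted p under 0.05, where 241.6 would be expected if no gene differed. Different clusters held the cells: 24 and 5 (58.7% and 31.7%) in spleen replicate 1, and 5, 3 and 1 (63.4%, 18.0% and 13.7%) in replicate 2.

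Cell cycle genes rose in the spleen in 22 of 24 cases, 23 when adjusted over the list alone, with a median of 5.99, or 4.83 with bounds (camera adjusted p = 2.84e-28; adjusted p = 0.199 with an estimated correlation). Secondary granule genes rose in 7 of 10, also over the list alone (4.94, camera adjusted p = 0.000292; adjusted p = 0.504 with an estimated correlation). Primary granule genes rose in 4 of 7, with 5 higher and 1 lower over the list alone (2.07, or 2.09 with bounds, camera adjusted p = 0.0114; adjusted p = 0.378 with an estimated correlation). Elane, at least 33.9-fold higher, and Mpo, at least 4.28-fold higher, were at 0 in spleen replicate 1. Interferon-response genes fell in 14 of 26 cases, 20 over the list alone (−2.06, camera adjusted p = 8.88e-09; adjusted p = 0.199 with an estimated correlation). Trafficking receptors fell in 9 of 18, also over the list alone (−1.24, camera adjusted p = 0.000683; adjusted p = 0.199 with an estimated correlation). Among them were the formyl peptide receptor Fpr1 (−2.60 ± 0.56) and Ccr1 (−2.58 ± 0.60). Immediate early genes fell in 3 of 24, 5 over the list alone (−1.13, camera adjusted p = 0.00703; adjusted p = 0.516 with an estimated correlation). They included Ier3 (−4.90 ± 0.83). NF-kB genes fell in 3 of 23, 4 over the list alone (−1.27, or −1.25 with bounds, camera adjusted p = 0.0199; adjusted p = 0.575 with an estimated correlation). Gelatinase granule genes fell in 2 of 7, 4 over the list alone (−1.15, camera adjusted p = 0.0393; adjusted p = 0.586 with an estimated correlation). Oxidative phosphorylation genes rose in 3 of 29, also over the list alone (0.58, camera adjusted p = 0.00138; adjusted p = 0.586 with an estimated correlation). Ribosomal protein genes rose in 3 of 92 and 0 over the list alone (0.37, camera adjusted p = 0.000336; adjusted p = 0.702 with an estimated correlation). The antigen presentation list, with 3 of 16 genes lower and 4 over the list alone, and the survival list, with 2 of 16 lower, did not pass (camera adjusted p = 0.306 and 0.106). Neither did the angiogenesis, glycolysis, NADPH oxidase and clock lists (0.781, 0.946, 0.28 and 0.846); the glycolysis test pointed upward against a median of −0.33. In mature clusters alone no member of any list was called, and the cell cycle, granule, trafficking, NF-kB and immediate early lists no longer passed (camera adjusted p = 0.635 for the cell cycle); the gelatinase list turned upward (0.928). Platelet markers were lower in the spleen sums in 7 of 7 cases, 4 of 12 macrophage markers were higher and 1 lower, and 5 of 9 progenitor markers were higher.

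Marrow and spleen neutrophils, set against each other, gave no called gene in edgeR. There were 205 genes at an unadjusted p under 0.05, where 397.1 would be expected if no gene differed. The smallest edgeR adjusted p was 0.0539, and DESeq2 called 3 genes. Primary granule genes had a median of 1.59 in favour of the marrow, with 4 of 7 members higher when adjusted over the list alone (camera adjusted p = 3.49e-07; adjusted p = 0.199 with an estimated correlation). Antigen presentation genes had a median of −0.23, with 4 of 16 lower over the list alone (camera adjusted p = 1.03e-05; adjusted p = 0.376 with an estimated correlation). Interferon-response genes had a median of −0.33 (camera adjusted p = 0.00472; adjusted p = 0.376 with an estimated correlation). The angiogenesis list had a median of 0.94, or 0.63 with bounds (camera adjusted p = 0.0428; adjusted p = 0.376 with an estimated correlation), and in mature clusters alone its adjusted p was 0.623. The other 12 lists did not pass; of these the NF-kB and clock tests pointed downward with medians of 0.26 and 0.12. Leaving out marrow replicate 2 gave 14 called genes, and leaving out spleen replicate 1 gave 3.

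Lung neutrophils differed from blood neutrophils most clearly in inflammatory mediators. Ccrl2 (ENSMUSG00000043953, chromosome 9, 111054486 to 111057519), a chemerin-binding receptor, was at 434 ± 161 CPM against 4.11 ± 0.926 in blood ZT13 (SD, n = 2; log2 6.77 ± 0.95). Ptgs2 (chromosome 1, 150100031 to 150108227), the inducible cyclooxygenase, was at 653 ± 127 against 7.17 ± 8.45 CPM (log2 6.34 ± 0.96). G0s2 (chromosome 1, 193272161 to 193273217), an inhibitor of triglyceride lipase, was at 3930 ± 1399 against 294 ± 108 CPM (log2 3.74 ± 0.55). All 3 had an edgeR Benjamini-Hochberg adjusted p of 0.00982. The fourth called gene, Scgb1a1, a secretory protein of airway club cells, was at 2149 CPM in lung replicate 2 and 0 in replicate 1. It was named outside the rule, after its values were seen. At an unadjusted p under 0.05 there were 621 genes, where 397.1 would be expected if no gene differed. DESeq2 called 30, of which 60% were higher. Cluster 24 held 98.9% and 82.8% of the lung cells and 98.4% of those of blood ZT13 replicate 2, and cluster 32 held 99.4% of those of blood ZT13 replicate 1. The count was 1 without lung replicate 1, 0 without lung replicate 2, 40 and 123 without blood ZT13 replicates 1 and 2, and 0 without the ZT5 library. Ccrl2, Ptgs2 and G0s2 stayed called without either blood ZT13 library and were lost without either lung library or the ZT5 library.

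Inflammatory NF-kB genes rose in 2 of 23 cases, 7 when adjusted over the list alone, with a median of 1.91 (camera adjusted p = 1.06e-09; adjusted p = 0.199 with an estimated correlation). Mature neutrophil markers made up 3 of the 25 listed genes. Cxcl2, a neutrophil chemoattractant, was at 2452 ± 732 against 49.6 ± 31.0 CPM (SD, n = 2; log2 5.65 ± 1.05, adjusted p = 0.053). No immediate early gene was called over all genes and 4 of 24 were higher over the list alone, with a median of 0.54 (camera adjusted p = 1.36e-06; adjusted p = 0.289 with an estimated correlation). The ribosomal list passed upward although its median was −0.03 and its mean −0.21 (camera adjusted p = 0.000211, and 0.702 with an estimated correlation). The median over all 7942 genes was −0.363 in this comparison. Upward in camera is relative to the other genes, so it can mean less negative than the rest and not higher in the lung. The angiogenesis list passed upward with a median of −0.37, a mean of 0.27 and 1 of 11 members higher over the list alone (camera adjusted p = 0.0404; adjusted p = 0.376 with an estimated correlation). With bounds its median was 0.33, and in mature clusters alone the adjusted p was 0.0565. Survival genes had a median of 0.07, with 2 higher and 1 lower over the list alone (camera adjusted p = 0.0393; adjusted p = 0.289 with an estimated correlation). Of the lists that did not pass, interferon-response and trafficking genes had medians of −0.90 and −0.70, each with 4 members lower over the list alone (camera adjusted p = 0.391 and 0.404). The clock list had a median of 1.19 (0.0534). The cell cycle, primary, secondary and gelatinase granule, glycolysis, oxidative phosphorylation, NADPH oxidase and antigen presentation lists had camera adjusted p of 0.762, 0.852, 0.843, 0.651, 0.235, 0.535, 0.762 and 0.304. The cell cycle, oxidative phosphorylation and antigen presentation tests pointed upward against medians of −0.86, −0.20 and −0.47.

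**Figure D3:**
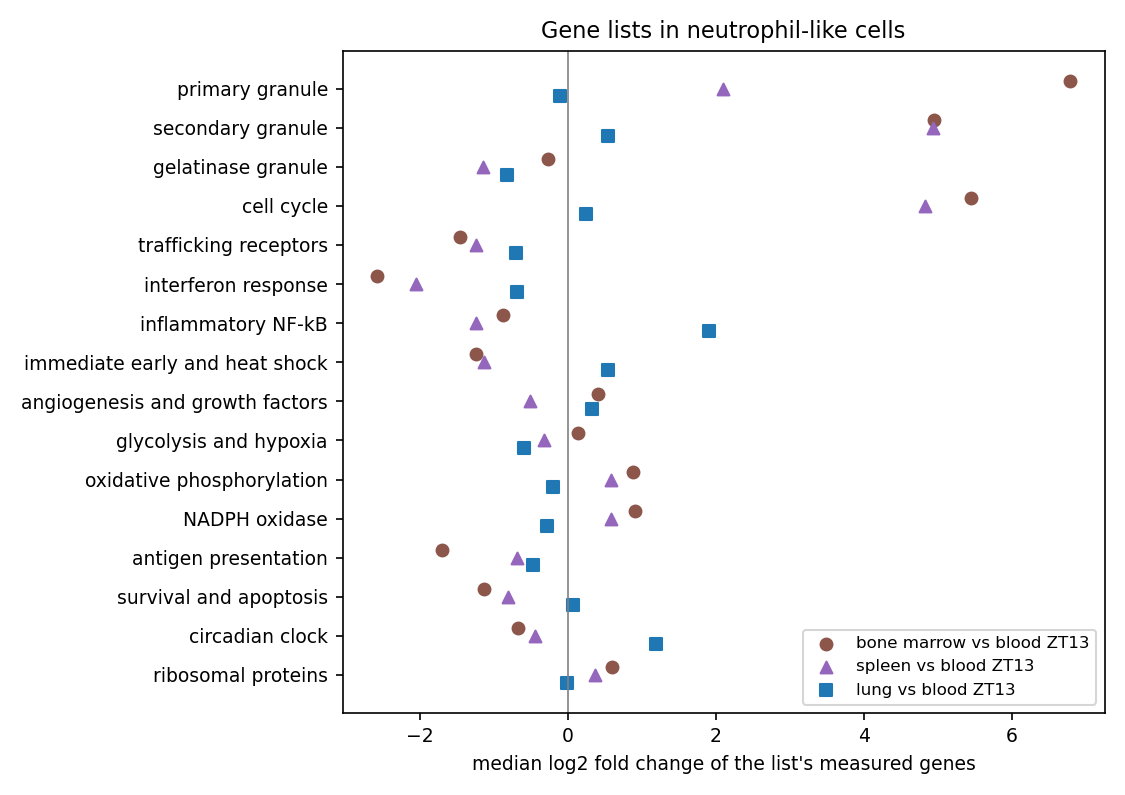
Median log2 fold change of the measured members of each of the 16 gene lists in neutrophil-like cells of bone marrow, spleen and lung, each against blood ZT13, with genes at 0 in one group set to their bound. Cell cycle and primary and secondary granule lists lie to the right in marrow and spleen (5.45 and 4.83 for the cell cycle), the gelatinase granule list to the left (−0.27 and −1.15), and the NF-kB list lies at 1.91 in the lung.

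Lung and spleen neutrophils differed in the same inflammatory list and in the cell cycle. Cxcl2 was at 2452 ± 732 CPM in the lung (SD, n = 2) and 0 in both spleen libraries, at least 918-fold higher. Cd14, the lipopolysaccharide coreceptor, rose by 5.38 ± 0.95 log2 units and the kinase Pim1 by 3.62 ± 0.51 (adjusted p = 0.00347). The amplifying receptor Trem1 rose by 5.06 ± 0.73, and the transcription factors Csrnp1 and Ets2 by 5.23 ± 0.77 and 4.95 ± 0.80. Ccrl2 and Ptgs2, with 2 and 3 counts in the spleen, had ratios of 261 (95% counting interval 70.5 to 2190) and 235 (78.8 to 1150). Fcnb, Ube2c and Birc5 were at 0 in the lung, at least 25.0-fold, 19.6-fold and 12.4-fold lower. No lung cell, of 94 and 29 neutrophil-like cells, fell into an immature cluster at Leiden resolution 1.0. At resolution 0.5, 1 cell of lung replicate 1 did. In lung replicate 2, 5 of the 29 sat in mature cluster 0, which held 906 cells of marrow replicate 1. Immature neutrophil markers summed to 7334 and 60380 CPM in the lung libraries, against 115800 and 193700 in the spleen and 29000 and 15930 in blood ZT13. In edgeR 104 genes were called, 47 higher and 57 lower in the lung. The count was 1 and 6 without lung replicates 1 and 2, 258 without spleen replicate 1, 0 without spleen replicate 2, 48 without the ZT5 library and 2 in mature clusters alone. Of 32 named genes, 0 and 2 stayed called without lung replicates 1 and 2, and 0 without spleen replicate 2.

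NF-kB genes rose in the lung against the spleen in 8 of 23 cases, 16 when adjusted over the list alone, with a median of 3.35, or 3.30 with bounds (camera adjusted p = 1.06e-09; adjusted p = 0.199 with an estimated correlation). Immediate early genes rose in 4 of 24, 14 over the list alone (1.59, camera adjusted p = 2.31e-09; adjusted p = 0.199 with an estimated correlation). Among them were the transcription factors Nr4a1 (5.22 ± 1.12) and Egr1, with 3 counts in the spleen (ratio 76.7, 95% counting interval 24.6 to 386). Cell cycle genes fell in 15 of 24, 21 over the list alone (−9.42, or −2.28 with bounds, camera adjusted p = 6.75e-15; adjusted p = 0.199 with an estimated correlation). Secondary granule genes fell in 2 of 10, 7 over the list alone (−2.83, camera adjusted p = 0.00746; adjusted p = 0.586 with an estimated correlation). Isg15 rose by 2.64 ± 0.48 and was the 1 called interferon-response gene of 26, also over the list alone (1.09, camera adjusted p = 1.65e-05; adjusted p = 0.199 with an estimated correlation). Survival genes rose in 2 of 16, 3 over the list alone (1.35, camera adjusted p = 0.00501; adjusted p = 0.199 with an estimated correlation). No trafficking receptor was called and 3 were higher and 3 lower over the list alone (0.97, camera adjusted p = 0.0304; adjusted p = 0.272 with an estimated correlation). That list turned downward in mature clusters alone (0.401). No oxidative phosphorylation gene was called and 1 of 29 was lower over the list alone (−0.84, camera adjusted p = 0.0409; adjusted p = 0.709 with an estimated correlation). Vegfa, the vascular growth factor, rose with 2 counts in the spleen (ratio 28.7, 95% counting interval 6.27 to 267), and Cybb fell by 3.33 ± 0.75, in lists that did not pass (0.0534 and 0.28). Primary granule genes fell in 1 of 7, 3 over the list alone, in a list that did not pass (0.0749). Mature neutrophil markers were higher in 4 of 27 cases and immature ones lower in 3 of 17. In mature clusters alone the NF-kB, immediate early and survival lists still passed (camera adjusted p = 2.13e-06, 1.27e-06 and 0.0213). The cell cycle, secondary granule, interferon and oxidative phosphorylation lists did not (0.951, 0.496, 0.564 and 0.496).

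Against marrow neutrophils, lung neutrophils showed higher inflammatory and immediate early transcripts and fewer of primary and secondary granule proteins and the cell cycle. Junb, a subunit of the AP-1 transcription factor, was at 4656 ± 1059 against 196 ± 98.9 CPM (SD, n = 2; log2 4.57 ± 0.81). Cd14, Nfkbiz, Nr4a1 and Btg2 rose by 5.12 ± 0.80, 3.61 ± 0.58, 5.21 ± 0.89 and 3.38 ± 0.62. Elane was at least 30.3-fold, Fcnb at least 38.6-fold and Ube2c at least 21.9-fold lower, and Cybb fell by 3.40 ± 0.75. In edgeR 297 genes were called, 144 higher and 153 lower, or 48.5% higher against 59.2% with DESeq2 size factors. The count was 1 and 9 without lung replicates 1 and 2, 147 without marrow replicate 2, and 72 (66 higher, 6 lower) in mature clusters alone. Of 37 named genes, 0 and 3 stayed called without lung replicates 1 and 2.

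NF-kB and immediate early genes rose in the lung against the marrow in 11 of 23 and 11 of 24 cases, 15 of each over the list alone (medians 2.95 and 2.58, camera adjusted p = 4.76e-12 and 2.91e-11; adjusted p = 0.199 for both with an estimated correlation). Interferon-response genes rose in 2 of 26, 10 over the list alone (1.85, or 1.94 with bounds, camera adjusted p = 1.09e-08; adjusted p = 0.199 with an estimated correlation). Survival genes rose in 4 of 16, 7 over the list alone (1.22, camera adjusted p = 0.000473; adjusted p = 0.199 with an estimated correlation). Antigen presentation genes rose in 3 of 16, 4 over the list alone (0.90, camera adjusted p = 6.01e-05; adjusted p = 0.413 with an estimated correlation). The last were led by Cd74, the invariant chain of class II molecules (3.37 ± 0.69), and 3 of 9 dendritic cell markers were also higher. Of 5 clock genes 1 rose, the transcription factor Nfil3 (2.56 ± 0.58), 2 over the list alone (0.50, camera adjusted p = 0.0428; adjusted p = 0.366 with an estimated correlation). Trafficking receptors had 1 higher and 1 lower, 7 and 4 over the list alone (1.04, or 1.18 with bounds, camera adjusted p = 0.00717; adjusted p = 0.199 with an estimated correlation). This list did not pass in mature clusters alone (0.573). Cell cycle genes fell in 18 of 24, 22 over the list alone (−9.82, or −2.56 with bounds, camera adjusted p = 2.75e-15; adjusted p = 0.199 with an estimated correlation). Primary granule genes fell in 5 of 7, with 6 lower and 1 higher over the list alone (−11.70, or −3.38 with bounds, camera adjusted p = 0.00244; adjusted p = 0.336 with an estimated correlation). Secondary granule genes fell in 2 of 10, 8 over the list alone (−3.19, camera adjusted p = 0.0102; adjusted p = 0.605 with an estimated correlation). Oxidative phosphorylation genes fell in 1 of 29, 10 over the list alone (−1.02, camera adjusted p = 0.0108; adjusted p = 0.661 with an estimated correlation). The NADPH oxidase list, with 3 of 6 genes lower and 4 over the list alone, did not pass (0.137). Neither did the glycolysis, ribosomal, gelatinase granule and angiogenesis lists (0.126, 0.472, 0.593 and 0.167); the gelatinase test pointed upward against a median of −0.77. Mature neutrophil markers were higher in 6 of 27 cases, and immature and progenitor markers lower in 4 of 17 and 5 of 9.

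A tissue-enriched gene was defined as higher in a tissue than in each of the other 3. The lung had 4 such genes, with smallest log2 differences of 6.03 for Ptgs2, 5.90 for Ccrl2 and 2.80 for G0s2, and Scgb1a1 as above. The marrow, the spleen and blood ZT13 had 0, while DESeq2 gave 6 for blood ZT13 and 16 for the lung. The lung count was 1 without lung replicate 1, 0 without lung replicate 2, without spleen replicate 2 or without the ZT5 library. It was 12 and 11 without marrow replicates 1 and 2, and 15 without either blood ZT13 replicate. The blood count was 15 and 13 without marrow replicates 1 and 2 and 22 and 54 without blood ZT13 replicates 1 and 2. The marrow count was 3 without marrow replicate 2 and 4 without either blood ZT13 replicate.

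**Figure D4:**
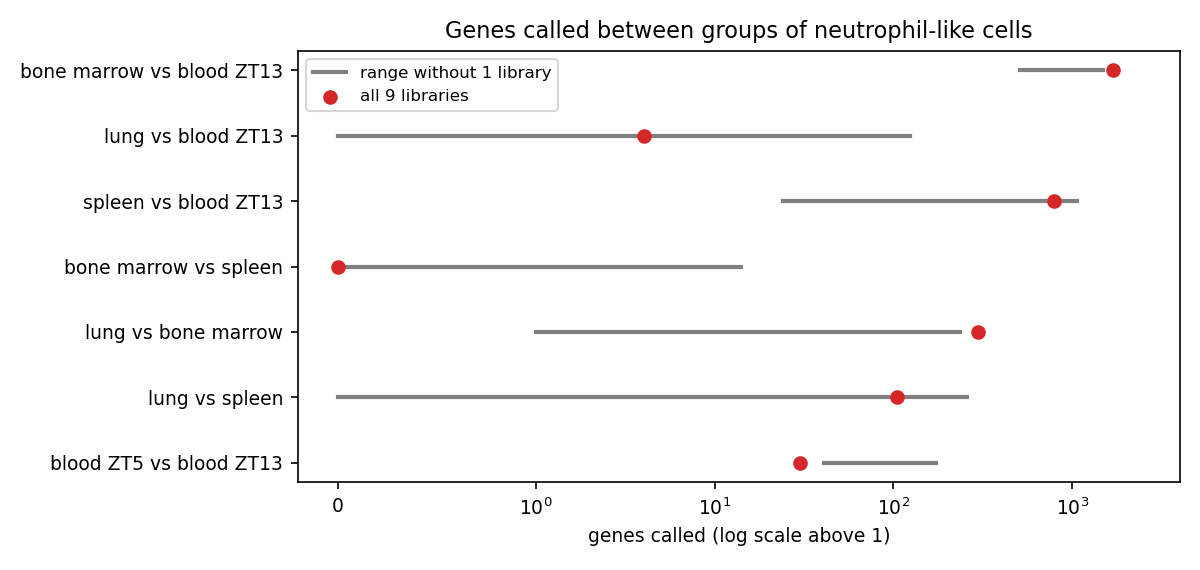
Number of genes called in each of the 7 comparisons of neutrophil-like cells (points) and the range of that number when 1 library of the groups compared, or the ZT5 library, is left out (bars), on an axis that is logarithmic above 1. The comparisons with the lung range from 0 or 1 to 123, 236 and 258 genes, and the marrow against blood comparison from 513 to 1485.

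The blood comparison by time point set the single ZT5 library against the ZT13 pair; the ZT5 library is assumed to vary like the other groups. The named genes that rose at ZT5 were Tsc22d1 (4.22 ± 0.65), Nrgn (4.21 ± 0.60), Gng11 (4.21 ± 0.71) and Bin1 (4.13 ± 0.68), each with an edgeR adjusted p of 0.016, and Ctla2a (3.66 ± 0.70, 0.0301). Tsc22d1, Nrgn, Gng11 and Ctla2a were each among the 10 leading genes of all 3 platelet-led clusters. Platelet markers summed to 8802 CPM in the ZT5 neutrophil-like cells, against 180 and 2118 CPM at ZT13 and at most 53.7 CPM in the other tissues. Called higher were 1 of the 7 platelet, 1 of 5 erythroid, 1 of 4 B cell and 1 of 2 plasma cell markers. Erythroid markers summed to 3034 CPM at ZT5 and to 627 and 2754 CPM at ZT13. Gbp2 was the 1 gene that fell, by 3.46 ± 0.73 (adjusted p = 0.0488). In edgeR 30 genes were called, 29 higher and 1 lower, against 17 by DESeq2, 82.4% of them higher. The count was 0 when only the blood libraries entered the fit, 174 without blood ZT13 replicate 2 and 12 in mature clusters alone. Interferon-response genes fell in 1 of 26 cases, 3 over the list alone (−0.78, camera adjusted p = 0.000676; adjusted p = 0.313 with an estimated correlation). No cell cycle gene was called, nor over the list alone, although the list passed upward (0.09, or 0.18 with bounds, camera adjusted p = 0.0186; adjusted p = 0.639 with an estimated correlation). It turned downward in mature clusters alone (0.46). None of the 5 clock genes, the list closest to the question of time of day, was called (−0.26, camera adjusted p = 0.762). The other 13 lists did not pass; the angiogenesis test pointed upward against a median of −0.34 and the NADPH oxidase test downward against 0.16.

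Monocyte-like cells, the other abundant myeloid class, gave few differences. In the lung, Lrg1, a leucine-rich glycoprotein (chromosome 17, 56119678 to 56122001), fell by 6.41 ± 0.52 and Wfdc21 (chromosome 11, 83746940 to 83752642) by 6.03 ± 0.51 log2 units against blood ZT13 (edgeR adjusted p = 0.0249 for both; n = 2 per group), the 2 called genes of 9950. Both calls were lost without either lung library. Neutrophil transcripts moved with these calls, as values chosen after the result was seen show. Wfdc21 is among the immature neutrophil markers, and Lrg1 among the leading genes of cluster 32, mature neutrophils of which 463 of 470 came from blood ZT13 replicate 1. Retnlg, a mature neutrophil marker, was at 214 and 2982 CPM in the blood and at 2.69 and 20.8 CPM in the lung monocyte-like sums. The primary, secondary and gelatinase granule lists were lower there too, with 0 of 7, 1 of 9 and 1 of 6 members above 0 (camera adjusted p = 0.0248, 0.0328 and 0.019; adjusted p = 0.597, 0.508 and 0.508 with an estimated correlation). DESeq2 called 41, and the count was 169 and 68 without blood ZT13 replicates 1 and 2. Spleen against blood gave 0 called genes, with 616 at an unadjusted p under 0.05 and 34 by DESeq2, and 298 and 50 without blood ZT13 replicates 1 and 2. The marrow, with 1 library of enough monocyte-like cells, also gave 0 against blood, with 937 at an unadjusted p under 0.05 and 87 by DESeq2, and 666 and 9 without blood ZT13 replicates 1 and 2. In each of these comparisons 497.5 genes would have an unadjusted p under 0.05 if none differed. Different clusters held the monocyte-like cells: 15 in marrow replicate 2 (96.6%) and 8 and 16 in the lung. Cluster 8 led in blood ZT13 replicate 1 (71.9%) and spleen replicate 1 (80.6%), 22 led in blood ZT13 replicate 2 (99.9%) and 20 in spleen replicate 2 (73.8%).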

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

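The tests of free platelet RNA, of time of day, of mixed-in marrow cells and of a change in all lung cells were chosen only after the result was seen; those of index hopping, attached platelets and free RNA in the lung were set beforehand.

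In blood ZT5, 22.4% (95% exact interval 21.4 to 23.3) of kept cells fell into platelet-led clusters, which no comparison used, against at most 0.234% in any other library. Platelet transcripts also stood in the neutrophil-like cells of that library. Free platelet RNA would give all cell types a like number of these UMIs, but neutrophil-like cells held 15.6 per cell and NK-like cells 0.978, a ratio of 16.0, at median depths of 1488 and 1936 UMIs, which argues against it. The ratio may be too high, since clustering can take platelet-bearing cells out of one class or gather them in another. Mature cluster 24 held 89.1% of the ZT5 neutrophil-like cells. It had the platelet marker Ppbp among its 10 leading genes and 5 platelet markers among its top 50. Unnamed cluster 21, with 66 ZT5 cells, had 10 NK and 5 platelet markers among its top 50 genes. Platelet-led clusters 30 and 31 had 3 and 7 monocyte markers, so they may include leukocytes with platelets. Attached or co-captured platelets would give an uneven number per cell, and the variance was 16.9 times the mean, which is consistent with them; doublets of a platelet and a neutrophil would look the same. Time of day cannot be told apart from handling, because the ZT13 libraries differed from each other 11.8-fold in platelet CPM and ZT5 was a single library, 4.16-fold above the higher of them.

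In lung replicate 2, Scgb1a1, a transcript of airway club cells, made up 31.2% of the UMIs in the 78 cells of a mixed cluster that no comparison used; 18 of these cells had it above 10% of their UMIs, and no other library had any.

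The inflammatory NF-kB list differed between lung and spleen neutrophil-like cells, tested as lung against spleen (camera adjusted p = 1.06e-09; adjusted p = 0.199 with an estimated correlation). Free RNA from other lung cells would leave these transcripts lower in neutrophil-like than in other cells, but the median ratio over 23 members was 3.16 and 2.19 in the lung libraries, which argues against it for the list as a whole. Only 14 and 15 members were above 1, and 3 of the 25 listed genes were mature neutrophil markers used to name these cells. Ptgs2 and Cxcl2 were among the 10 leading genes of macrophage cluster 23, with 31 and 256 cells of the lung libraries. The list median does not settle free RNA for such single genes. A change in all lung cells, as enzyme digestion could give, is consistent with the list medians against blood ZT13, which were 0.68 in monocyte-like and 0.95 in NK-like cells, against 1.91 in neutrophil-like cells. Only lung was digested, so tissue and digestion cannot be separated here, and an effect of the lung itself stays open and untested.

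The cell cycle list also differed between lung and spleen (camera adjusted p = 6.75e-15, and 0.199 with an estimated correlation). In mature clusters alone it did not (camera adjusted p = 0.951), but only 10 of its 24 members were measured there. Ube2c was among the 10 leading genes of immature cluster 3, so leaving immature clusters out removes cycling cells in advance and decides nothing. The cell cycle list moved with the immature cells, which were 81.3% of the neutrophil-like cells of spleen replicate 2. Index hopping from marrow replicate 2 would make their barcodes recur there, but 0.433% did (1 of 231), against 0.972% of the other cells (Fisher's exact test, two-sided p = 0.726), which argues against it. Marrow cells mixed into the spleen sample could not be excluded: of the monocyte-like cells of cluster 15 that would come along, 4 (95% Poisson interval 1.09 to 10.2) were seen where 56.0 were predicted. That cluster is 99.0% marrow replicate 2, so it may follow the library rather than the tissue. This reason to set the test aside was written after its value was seen. Other marrow-rich clusters were present, as values chosen later show. Unnamed clusters 7 and 2 and progenitor cluster 4 held 47, 84 and 8 cells of spleen replicate 2. In marrow replicate 2 they held 515, 263 and 293, beside 3437 immature neutrophil-like cells there and 231 in the spleen library. These counts do not tell mixing from cells formed in the spleen. Granulocyte formation in the spleen stays open and untested.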

How the results depend on the processing

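The alternatives of doublets removed at the expected rate, Leiden resolution 0.5, no ZT5 library and list tests in mature clusters alone were chosen only after the results were seen. Counts of called genes are given where they moved by over 1.5 times; the cause was not tested, except that thinning, leaving libraries out and mature clusters leave fewer counts. One library left out is always one of the groups compared, and leaving out ZT5 is given apart. Neutrophil shares moved under no alternative by more than their interval; of 97 class shares, 22 moved with Leiden resolution 0.5, 7 with doublets at the expected rate, 4 with no cell filter and 2 with doublets kept. The split of neutrophil-like cells into mature and immature depended on the Leiden resolution, as given above. The filter at 500 UMIs removed no cell and tests nothing. Depth limits the lung most, at 55845 UMIs in its smaller neutrophil-like sum.

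For marrow against blood (1686) the count was 976 with DESeq2, 53 with thinned sums, 296 in mature clusters and 513 to 1485 without one library. For lung against blood (4) it was 30 with DESeq2, 100 with no low-count filter, 11 with doublets kept or removed at the expected rate, 10 with Leiden 0.5, 7 in mature clusters, 0 with all 3 blood libraries as one group or without ZT5, and 0 to 123 without one library. For spleen against blood (792) it was 22 thinned, 163 with only the groups compared, 0 in mature clusters and 24 to 1060 without one library. For marrow against spleen (0) it was 3 with DESeq2, 75 with no filter, 8 with doublets kept or at the expected rate, 7 with Leiden 0.5, 23 with only these groups and 0 to 14 without one library. For lung against marrow (297) it was 560 with no filter, 96 thinned, 991 with only these groups, 72 in mature clusters, 236 without ZT5 and 1 to 235 without one library. For lung against spleen (104) it was 196 with DESeq2, 302 with no filter, 31 thinned, 26 with only these groups, 2 in mature clusters, 48 without ZT5 and 0 to 258 without one library. For ZT5 against ZT13 (30) it was 17 with DESeq2, 151 with no filter, 1 thinned, 0 with only blood, 12 in mature clusters and 41 to 174 without one library.

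Monocyte counts against blood were, for marrow (0), 87 with DESeq2, 464 with no filter, 111 with Leiden 0.5, 0 without ZT5 and 9 to 666 without one library; for lung (2), 41, 267 with no filter, 5 thinned, 0 with only these groups or blood as one group, and 0 to 169; and for spleen (0), 34, 332 with no filter, 1 with blood as one group, and 0 to 298. Tissue-enriched sets were, for marrow (0), 5 with no filter, 2 with doublets kept, at the expected rate or with Leiden 0.5, and 0 to 4 without one library; for lung (4), 16 with DESeq2, 25 with no filter, 2 in mature clusters, 0 without ZT5 and 0 to 15; for spleen (0), 1 with no filter and 0 without any one library; and for blood (0), 6 with DESeq2, 42 with no filter, 2 with doublets kept, at the expected rate or with Leiden 0.5, and 0 to 54.

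With the replicate number as a replicate block, counts were 31 for lung against blood, 15 for marrow against spleen, 473 for lung against marrow, 199 for lung against spleen, 87, 39 and 37 for monocytes of marrow, lung and spleen, and 2, 12 and 12 for the marrow, lung and blood sets; 49 list tests passed. The labels do not say what the numbers mark. Deviations of same-numbered libraries correlated from −0.01 to 0.15. That gives no sign of pairing, but noise in the small sums would also lower these values, so pairing cannot be excluded.

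Of 112 list tests 51 passed, 0 with an estimated correlation and 42 in mature clusters, where 33 kept their call, 15 lost it and 3 turned: gelatinase genes in spleen against blood (adjusted p = 0.928, range over alternatives 0.0139 to 0.928 with the replicate block included), trafficking receptors in lung against spleen (0.401, range 0.0124 to 0.401) and the cell cycle at ZT5 (0.46, range 0.46 to 0.639). Mature clusters also turned Ube2c (−3.69), Birc5 (−3.17), Orm1 (−5.21), Chil3 (−0.42) and Cycs (−1.21) in spleen against blood and Orm1 (5.74) in lung against spleen, none called there. Bcl2a1a in marrow against blood was −2.39, and −3.15 to 0.55 without one library; it turned without blood ZT13 replicate 2 and was not called there.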

Other observations

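All tests of NK-like cells and of gene lists outside the neutrophil-like cells were chosen only after the neutrophil results were seen.

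NK-like cells differed between lung and spleen in 2 of 9079 genes by edgeR. The makeup of the class differed between libraries. Cluster 18 held 24.6% and 88.8% of these cells in the lung libraries and cluster 17 held 73.9% and 10.3%, against 98.2% in cluster 17 in both spleen libraries. In blood ZT13, cluster 17 held 90.2% in replicate 1 and cluster 14 held 99.5% in replicate 2, and cluster 14 held 97.2% in marrow replicate 2. Rgs2 (chromosome 1, 143999338 to 144004161), a regulator of G protein signalling, rose by 1.91 ± 0.19 log2 units (SE, n = 2 per group; adjusted p = 0.0313), and Tnfaip3 (chromosome 10, 19000910 to 19015657), an inhibitor of NF-kB signalling, rose by 3.42 ± 0.39 (0.0456). Both were higher in each lung library than in each spleen library. DESeq2 called 14 genes, 13 higher and 1 lower. Without lung replicate 1, 9 genes were called, and without spleen replicate 1, 45. Both calls were lost without lung replicate 2 (Rgs2 0.745, Tnfaip3 0.883) or spleen replicate 2 (0.713 for both). Over the alternatives run, the adjusted p of Rgs2 ranged from 3.42e-12 without a low-count filter to 0.745, and that of Tnfaip3 from 2.85e-25 to 0.883. Against the marrow, where 1 library had enough cells, Ltb, a lymphotoxin chain, fell by 2.89 ± 0.28 in lung NK-like cells (0.0252), a call lost without lung replicate 1 (0.0964) or 2 (0.683). No gene was called in NK-like cells of lung, spleen or marrow against blood ZT13, with 517, 502 and 805 genes at an unadjusted p under 0.05 and 10, 2 and 11 called by DESeq2. With no low-count filter 191, 198 and 141 genes were called. The absence of calls also did not hold without blood ZT13 replicate 1, while it held without replicate 2. In each of these comparisons 454 genes would have an unadjusted p under 0.05 if none differed.

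The 96 list tests in the other classes found shifts of whole lists with almost no member called. In the results below, 1 of 18 NF-kB genes was called, in NK-like cells of lung against spleen, and 0 members of the other lists. The immediate early list was higher in lung than in spleen in monocyte-like cells (median 1.30, 24 of 26 above 0, camera adjusted p = 3.47e-22, and 0.472 with an estimated correlation) and in NK-like cells (1.02, 23 of 26, camera adjusted p = 1.59e-11, and 0.508 with an estimated correlation). NF-kB genes did likewise, with medians of 1.21 in monocyte-like cells (21 of 22, camera adjusted p = 4.06e-12; adjusted p = 0.508 with an estimated correlation) and 1.37 in NK-like cells (16 of 18, camera adjusted p = 6.94e-07; adjusted p = 0.525 with an estimated correlation). Angiogenesis genes were higher in lung than in spleen monocyte-like cells (0.89, camera adjusted p = 9.32e-07; adjusted p = 0.472 with an estimated correlation). The cell cycle list was higher in lung than in blood NK-like cells, which sat in the different clusters given above, with 23 of 24 members above 0 and 0 called (0.76, camera adjusted p = 3.95e-09, and 0.508 with an estimated correlation). Interferon-response genes were higher in spleen than in blood monocyte-like cells, with 21 of 26 above 0 (0.42, camera adjusted p = 1.01e-05; adjusted p = 0.508 with an estimated correlation).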
